A study of Caenorhabditis elegans with 4 samples.

How the data were processed

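Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed by the submitters on whole Caenorhabditis elegans hermaphrodites at the late embryonic stage. The strain, OP372, carries an integrated transgene in which K09A11.1 is fused at its C terminus to GFP and FLAG tags, and an antibody against GFP was used for the precipitation after sonication, per the labels. The group holds 4 libraries from 2 biological replicates with 2 technical libraries each. Every library belongs to this one group, so no comparison between groups was made. Each comparison below sets the peaks against the genome annotation or the lists of the biological replicates against each other.

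The deposited files are peak lists on genome builds ce11 and ce10, per the labels. For each build they hold ranked lists of candidate regions for replicate 1, replicate 2 and both together (the pooled list), and a thresholded list kept by the irreproducible discovery rate (IDR), a measure of rank reproducibility. Each ranked list holds 30000 regions. The technical libraries of a replicate were merged into 1 alignment before calling, and both replicates were called against the same control, per the deposited notes that accompany the lists. The aligner, the peak caller, its version and the IDR threshold are not given in the sources used here. The signal value of each region is the authors' own, as deposited, and was used to rank and describe regions within a list. Signal values of the replicate lists are also given side by side, as deposited, without scaling 1 list to the other. The column of −log10 q-values was deposited by the authors as well, and lies between 2.39 and 3.00 in the thresholded list. The lists give no read counts, so sequencing depth is unknown and the precision of single signal values could not be computed.

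The thresholded list on ce11 was found to be the 689 regions of highest signal in the pooled list, with all 689 rows unchanged. The thresholded list on ce10 holds 705 peaks, of which 330 share their interval with the ce10 pooled list. The reference assembly WBcel235 is the build named ce11, and every region fitted inside its chromosome. Locations therefore come from the ce11 lists and the Ensembl release 115 annotation of WBcel235, with tRNA products from the RefSeq annotation of the same assembly. The ce10 list was used only for counts of peaks and chromosome shares.

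Of the 689 peaks, 26 lie on the mitochondrial genome and were left out of the main location and gene tests, which used the 663 nuclear peaks. A promoter was the window from 1000 bp upstream to 200 bp downstream of an annotated 5' end of a protein-coding transcript. Shares of peaks at promoters, in exons, introns and between genes, in the third of each autosome around its centre, at divergent promoters and near noncoding genes were compared with 10000 circular shifts of all summits along each chromosome, a permutation test whose smallest two-sided p is 0.0002. Chromosome shares were compared with the share of protein-coding genes by exact binomial tests. Gene lists were tested with Fisher's exact test on genes with a promoter peak against all other protein-coding genes of the 6 nuclear chromosomes. There were 33 lists, including markers of epidermis, muscle, pharynx, neurons, intestine and germline. Words of 6 bases were counted in 101 bp windows at the summits and in equal windows 200 bp away, on a side drawn at random, and compared with exact sign tests. A set of 29 known binding motifs was tested in the same way and adjusted over that list alone. Lists of the replicates were compared by the share of the 663 highest nuclear regions with summits within 100 bp, against 1000 circular shifts, for which the smallest one-sided p is 0.001. All adjusted p-values are from the Benjamini-Hochberg method with a threshold of 0.05, and intervals are exact 95% binomial (Clopper-Pearson) intervals that treat peaks or genes as independent. Peaks and genes are not biological replicates, so these tests describe this list of peaks.

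Items named in the text are the 25 peaks of highest signal with the protein-coding gene of nearest 5' end, up to 4 members with the highest promoter peaks of each gene list past the threshold, and K09A11.1. The snoRNA genes at the 25 peaks are named with them. Many of the named list members share their peak with the promoter windows of other protein-coding genes. Such a peak cannot be given to the named gene alone. Other genes in the text are marked as named after their values were seen, and the single words of 6 bases were also chosen then. The restriction to nuclear peaks was chosen after the data were examined. The tests of exons, introns and intergenic sequence, of GC content and of tRNA products were not part of the fixed plan. Nor were the tests of the X share and of words within classes of peaks. The other tests, apart from those of explanations, were fixed before the data were examined, as were the lists and the other alternatives. Alternatives included the 331 strongest nuclear peaks, the 663 highest nuclear regions of each replicate's list, other promoter windows, other backgrounds and other word windows. Where the list of a replicate alone is named below as an alternative, it means these 663 regions. Leaving out peaks at small RNA genes (also with chromosome length as the expectation for the X), in repeated sequence or with any repeated word, and including the mitochondrial peaks, were alternatives added after seeing the data.

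The computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. The tests were tested on simulated data. In 100 sets of 663 uniformly placed peaks, promoter enrichment was called in 4 sets, the share around autosome centres in 7, divergent promoters in 6, the X share against chromosome length in 5, a gene list in 3 and a noncoding class in 0, and in 20 such sets a word was called in 1. In the planted sets 30% of the peaks were placed at promoters, 15 of them at ribosomal protein genes, and 15 other peaks at tRNA genes. A word was planted in 40 summit windows. Each was recovered in 20 of 20 sets. Smaller effects were not simulated, nor were null sets with peaks clustered at promoters as in the data.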

Results

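K09A11.1 encodes a protein annotated with a BED-type domain, a zinc-binding domain found in DNA-binding proteins, and the question addressed was where in the genome of the late embryo the tagged protein is recovered. The data are 4 libraries in 1 group, from 2 biological replicates with 2 technical libraries each. The depth of each library is unknown, because the lists hold regions and signal values but no counts. The thresholded list held 689 peaks on ce11, of which 663 were nuclear and 26 mitochondrial. They hold 687 distinct intervals, because the mitochondrial peaks of rank 4, 19 and 24 by signal are summits of 1 interval. The commonest peak width was 340 bp, for 640 of the peaks. Signal values, which are the authors' own, ran from 30.4 to 452 with a median of 45.9.

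Many of the strongest sites were found in both replicates, with lower signal values in replicate 2, whose depth relative to replicate 1 is unknown. The peak upstream of idhg-1, a subunit of mitochondrial isocitrate dehydrogenase, had a signal of 169 in the replicate 1 list and 50.7 in the replicate 2 list. The peak upstream of atx-2, the ataxin-2 homologue that binds RNA, had 132 and 51.9. The peak upstream of rpl-3, a protein of the large ribosomal subunit, had 96.5 and 48.2. Of the 663 highest nuclear regions of replicate 1, 49.8% had a summit within 100 bp of one of the 663 highest of replicate 2, against 0.144% after shifting (permutation p = 0.001, one-sided, the smallest that the shifts allow). Both lists were called against the same control, so regions set by the control or by mapping could also recur in both, and the shifts give no expectation for these. The share was 54% for the 100 highest regions and 18.1% for the 5000 highest. Of the 663 nuclear thresholded peaks, 541 were among the 663 highest regions of replicate 1, 424 among those of replicate 2 and 335 among both. A region was listed within 100 bp in both replicate lists for 603 peaks, with a median signal of 30.1 in replicate 1 and 16.2 in replicate 2. Across these peaks, which are not independent replicates, Pearson's r of the log2 signals was 0.31 and Spearman's rho of the signals was 0.31. The peaks were selected by high pooled signal and by being listed in both replicates. The coefficients therefore do not measure agreement over all regions.

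**Figure D1:**
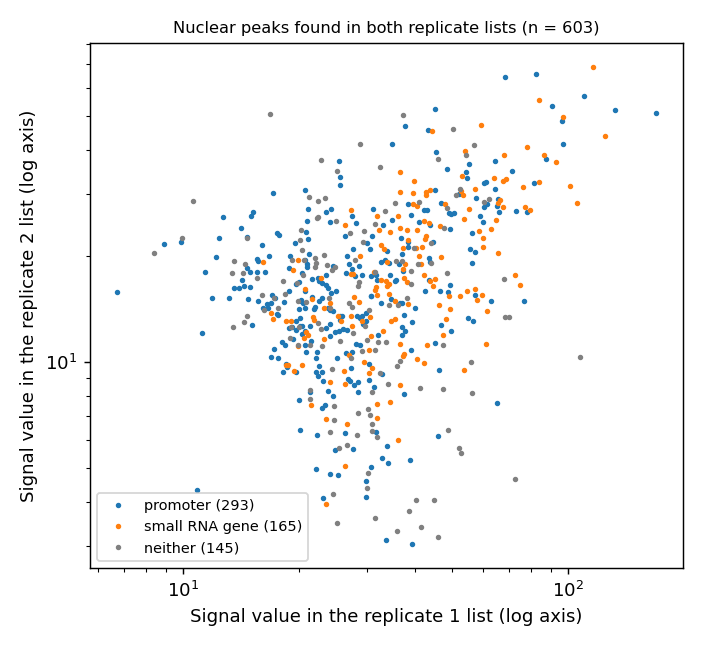
Signal value of 603 nuclear peaks in the replicate 1 list (x axis, log scale) and in the replicate 2 list (y axis, log scale), each point a peak, coloured by its class: at a promoter, at a small RNA gene or at neither. Values were higher in replicate 1, with medians of 30.1 and 16.2, and the points scatter widely, with a Spearman's rho of 0.31. These peaks were selected by high pooled signal.

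The strongest sites were mitochondrial regions, promoters of protein-coding genes, and snoRNA genes. Of the 25 peaks of highest signal, 17 were mitochondrial, 5 lay at promoters of protein-coding genes and 3 lay at snoRNA genes, which encode small RNAs that guide modification of other RNAs. On ce11, the strongest nuclear peak covered chromosome III 4568630 to 4568851, with its summit at 4568739 in the intergenic sequence 58 bp upstream of idhg-1 and a signal of 216. The atx-2 peak, at chromosome III 10461197 to 10461411, had its summit 77 bp upstream and a signal of 185. The next promoter peaks were at ears-2, a mitochondrial glutamyl-tRNA synthetase, on chromosome IV 390382 to 390579 with a signal of 162, and at ftt-2, a 14-3-3 protein, on chromosome X 11605802 to 11606076 with a signal of 146. The peak of rpl-3 covered chromosome III 3867567 to 3867663, had its summit 268 bp upstream and a signal of 145. The snoRNA gene pair C51F7.3 and C51F7.4 held a peak on chromosome V 12303574 to 12303721, inside an intron, with a signal of 180; the nearest protein-coding 5' end was that of F55C5.17. The snoRNA gene T03F7.8, in an intron on chromosome V and nearest to cutl-18, had a peak from 11314127 to 11314296 with a signal of 171. The snoRNA gene W03C9.9, next to W03C9.1 on chromosome II, had a peak from 11960726 to 11960890 with a signal of 146.

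Peaks lay in the promoter windows of genes far more often than shifted peaks did, and rarely in exons. Of the 663 nuclear peaks, 357 (53.8%, interval 49.97 to 57.7) had a summit in a protein-coding promoter, against 25.6% after shifting, which is 2.105-fold (permutation p = 0.0002, two-sided). Among the promoter peaks 94.7% were upstream of the nearest 5' end, at a median distance of -215 bp from it. The window reaches 1000 bp upstream and only 200 bp downstream, so evenly placed peaks would also lie mostly upstream. The upstream share was not tested. Exons of protein-coding genes held 19 peaks (2.87% against 29.3% after shifting, permutation p = 0.0002), introns held 192 (29.0% against 33.8%, permutation p = 0.0122) and intergenic sequence held 452 (68.2% against 36.9%, permutation p = 0.0002). Intergenic here means outside protein-coding genes, so noncoding genes that lie there were counted as intergenic. Many promoter peaks sat between genes transcribed away from each other. Of the 357 promoter peaks, 126 (35.3%) lay in the windows of such a divergent pair, against 8.71% after shifting (permutation p = 0.0002). These peaks cannot be given to 1 gene. Signal was not related to the distance from the nearest 5' end past the threshold, with Spearman's rho of 0.068 across peaks (permutation p = 0.0799, two-sided). The share at promoters was 52.6% in the fifth of highest signal and 61.4% in that of lowest signal.

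Ribosomal protein, chaperone and respiratory chain genes carried promoter peaks most often in the thresholded list, but the order below ribosomal proteins changed in some alternatives. A promoter peak was present at 498 of 19973 protein-coding genes, or 2.49%. Of 33 gene lists, 7 lay above the share of other genes and 2 below it at the adjusted threshold. Ribosomal protein genes stood highest, with 24 of 81 (29.6%, interval 19.99 to 40.8) against 2.38% of other genes (Fisher's exact test, adjusted p = 3.93e-18). Their strongest peaks were at rpl-3, at rps-28 on chromosome IV with a signal of 114.6, at rpl-35 on chromosome III with 93.8 and at rpl-20 on chromosome IV with 85.7. The summits of rps-28, rpl-35 and rpl-20 were 437, 414 and 283 bp upstream. Chaperone genes had peaks at 13 of 61 (21.3%, adjusted p = 4.48e-08, Fisher's exact test). These included hsp-60, the mitochondrial chaperonin, with a signal of 103, the DnaJ gene dnj-29 with 88.8, the constitutive Hsp70 gene hsp-1 with 68.8 and hsp-110 with 59.1. Respiratory chain and ATP synthase genes had peaks at 8 of 40 (20%, adjusted p = 4.44e-05, Fisher's exact test), led by the cytochrome c oxidase gene cox-5B with a signal of 89.3, followed by cox-6B with 64.3, cyc-1 with 51.6 and cox-6C with 51.6. With each peak given to the gene of the nearest 5' end alone, the shares were lower and stayed past the threshold: 17.3% of ribosomal protein genes (adjusted p = 3.25e-06), 14.8% of chaperone genes (adjusted p = 0.0012) and 15% of respiratory chain genes (adjusted p = 0.0078, Fisher's exact test for each).

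Smaller shares were found for other widely used complexes. Translation factor genes had peaks at 6 of 40 (15%, Fisher's exact test, adjusted p = 0.0024), with a signal of 72.7 at iff-2, 54.5 at the elongation factor gene eef-1A.1 (a peak also at a microRNA gene), 46.4 at eif-3.C and 42.1 at eef-1A.2. Chromatin genes had peaks at 11 of 110 (10%, Fisher's exact test, adjusted p = 6.32e-04). Among them swsn-3, of the SWI/SNF complex, had a signal of 136, the histone deacetylase gene hda-1 had 59.4, and the histone methyltransferase genes set-16 and set-25 had 45.3 and 44.3. At the set-25 peak, 100% of the 32-base words of the summit window recurred elsewhere in the genome, so reads there may not be placed uniquely. Its signal in the replicate 2 list was 8.09. Splicing genes had peaks at 6 of 59 (10.2%, Fisher's exact test, adjusted p = 0.0162), at lsm-3 with 67.6, rsp-3 with 39.2, lsm-7 with 33.8 and rsp-1 with 32.5. Their share was 5.08% in the list of replicate 1 alone (Fisher's exact test, adjusted p = 0.379) and 16.9% in that of replicate 2 (adjusted p = 2.32e-05), and it missed the threshold by the nearest 5' end (3.39%, adjusted p = 1) and among isolated promoters (5.56%, adjusted p = 0.554). Proteasome genes had peaks at 4 of 33 (12.1%, Fisher's exact test, adjusted p = 0.0364): rpn-7 with 75.2, rpn-3 with 59.1, rpt-2 with 39.7 and rpt-6 with 38.2. The rpn-3 peak is also the hsp-110 peak, since both genes share 1 promoter region. By the nearest 5' end the proteasome share was 6.06% and missed the threshold (Fisher's exact test, adjusted p = 0.585). Among the 331 strongest nuclear peaks only 3 of the 9 lists passed: ribosomal proteins, respiratory chain and chemoreceptors. With genes of isolated promoters as background, 6 of the 9 passed, and splicing, proteasome and secreted immunity genes did not. Proteasome genes, of which 6 have an isolated promoter, had a peak at 0 of these 6. The passes rest on few genes too, such as 4 of 20 ribosomal protein and 3 of 15 translation factor genes. For chaperones these were 3 of 27 and for respiratory chain genes 2 of 11.

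Chemoreceptor genes, which are expressed in few sensory neurons, had peaks at 6 of 1309 (0.458% against 2.64% of other genes, Fisher's exact test, adjusted p = 1.24e-07). The strongest were sre-23 with a signal of 127, at a snoRNA gene, sre-1 with 80.3, sri-5 with 55.2 and srh-16 with 47.7. The sre-1 summit lay 937 bp upstream, and the peaks of sre-1, sri-5 and srh-16 were each shared with 1 other gene. Secreted immunity genes had peaks at 2 of 363 (0.551%, Fisher's exact test, adjusted p = 0.0364), clec-53 with 76.6 and clec-126 with 59.2, the latter at tRNA genes. At the clec-126 peak, 71.4% of the 32-base words of the summit window recurred elsewhere in the genome. Against shifted peaks, in place of other genes, neither list was lower past the threshold, with 0.458% against 0.611% and 0.551% against 0.716% from the shifts (permutation test, adjusted p = 1 for both). The secreted immunity list also missed the threshold in the list of each replicate alone, with adjusted p = 0.0741 for replicate 1 and 0.0797 for replicate 2 (Fisher's exact test).

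Genes of single tissues did not stand apart. Muscle genes had peaks at 2 of 64, pan-neuronal genes at 3 of 56, intestinal genes at 1 of 44, germline genes at 1 of 77, epidermal regulators at 0 of 30 and pharyngeal genes at 0 of 41. None of these passed Fisher's exact test after adjustment, and the intervals are wide: a share of up to 11.6% of epidermal regulators and 10.8% of muscle genes remains possible. Among transcription factors, homeobox genes had peaks at 1 of 103, nuclear receptors at 4 of 274, bHLH genes at 3 of 39 and GATA, forkhead, SOX and T-box genes at 0 of 49. Cuticle collagens had 1 of 181, apical matrix genes 2 of 140, ciliary genes 0 of 68, neuropeptides 2 of 144, axon guidance genes 1 of 54 and Wnt, Notch and related signalling genes 1 of 58. Histone genes had 5 of 82, cell cycle genes 2 of 46, mitochondrial ribosomal proteins 3 of 70 and aminoacyl-tRNA synthetases 1 of 32. Detoxification genes had 2 of 215, lipid metabolism genes 0 of 88, lysosome and autophagy genes 4 of 90 and ubiquitin ligase adaptors 6 of 470. All of these lists missed the adjusted threshold.

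**Figure D2:**
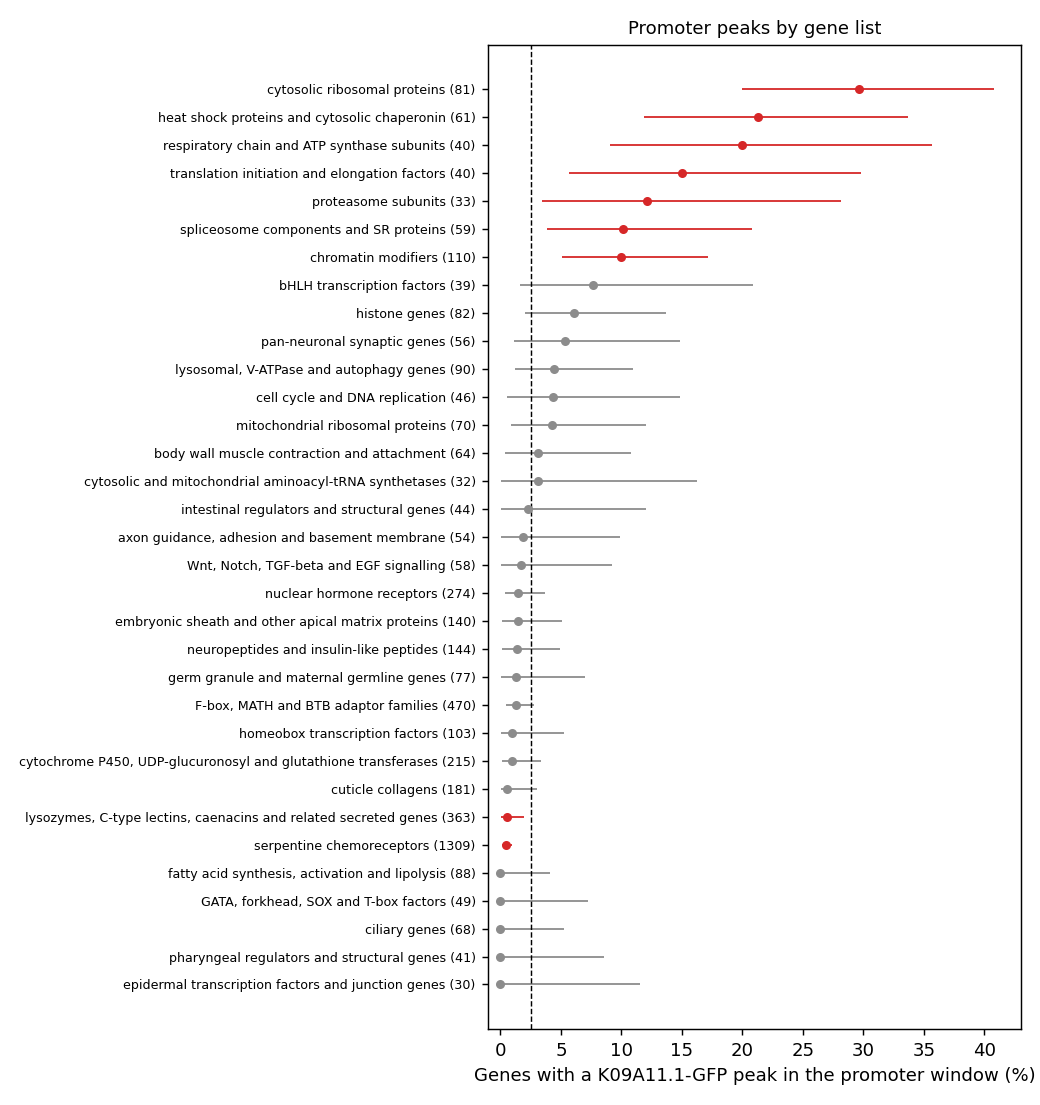
Share of the genes of each list with a peak summit in the promoter window (x axis, percent; points), with exact 95% intervals (bars) and the number of genes in parentheses; red points passed the adjusted threshold and the dashed line is the share of all protein-coding genes, 2.49%. Ribosomal protein genes lie highest at 29.6%, followed by chaperones at 21.3% and respiratory chain genes at 20%.

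Genes for small structural RNAs carried peaks far more often than shifted peaks would give. Summits lay within 200 bp of a tRNA gene for 123 peaks (18.6% of the 663) against 1.98 after shifting, and within 200 bp of a snoRNA gene for 44 peaks against 1.21 (permutation test, adjusted p = 0.00035 for each). The snRNA class had 8 peaks against 0.401 (permutation test, adjusted p = 0.00035), among them peaks at the spliced leader genes sls-2.1, sls-2.2, sls-2.4 and sls-2.8, named after their values were seen; in the list of replicate 2 alone the class had 5 peaks. At the sls-2.1 peak, 55.7% of the 32-base words of the summit window recurred elsewhere in the genome. MicroRNA genes had 5 peaks against 0.820 (permutation test, adjusted p = 0.0056). Genes of piRNAs had 4 peaks against 19.2 (permutation test, adjusted p = 0.00035), fewer than after shifting, and rRNA genes had 0 against 0.111. Long intergenic noncoding RNA genes had 3 against 2.12 (permutation test, adjusted p = 0.824). By gene, 133 of 612 tRNA genes (21.7%, interval 18.5 to 25.21) and 45 of 346 snoRNA genes (13.0%, interval 9.65 to 17.01) had a peak. The strongest tRNA peak, named after its value was seen, was at the tRNA-Asn gene F41D9.t3 in an intron on chromosome X, with a signal of 138. In its summit window 40% of the 32-base words recurred elsewhere in the genome. Summits at tRNA genes lay at a median of 24 bp downstream of the 5' end and inside the gene in 54.1% of cases. Those at snoRNA genes lay at a median of 46 bp upstream, and inside the gene in 11.11% of cases.

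**Figure D3:**
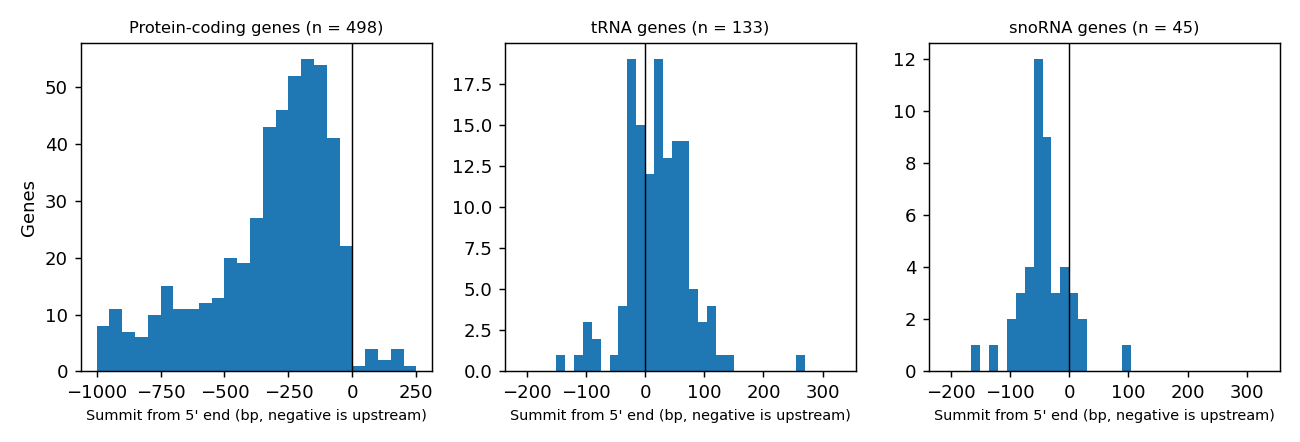
Position of the strongest peak summit relative to the annotated 5' end (x axis, bp, negative is upstream; y axis, number of genes) for 498 protein-coding genes, 133 tRNA genes and 45 snoRNA genes with a peak. Summits lie mostly upstream of protein-coding and snoRNA genes and around the start of tRNA genes, at a median of 24 bp inside. The window for protein-coding genes reaches 1000 bp upstream and only 200 bp downstream, so most of it is upstream.

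The X chromosome and chromosome III held more peaks than their share of protein-coding genes, and chromosome V held fewer. The X held 150 of the 663 peaks (22.6%, interval 19.5 to 26.003) against 13.7% of genes (exact binomial test, adjusted p = 1.51e-09). Chromosome III held 118 (17.8% against 13.2%, exact binomial test, adjusted p = 0.0017) and chromosome I also held 118 (17.8% against 14.4%, adjusted p = 0.0188). Chromosome V held 86 (13.0% against 25.004%, exact binomial test, adjusted p = 1.74e-13) and chromosome II held 91 (13.7% against 17.3%, adjusted p = 0.0188). Against chromosome length the X (17.7%, adjusted p = 0.0033), III (13.7%, adjusted p = 0.0066) and V (20.9%, adjusted p = 1.01e-06) stayed past the threshold, and I (15.03%, adjusted p = 0.0754) and II (15.2%, adjusted p = 0.304) did not (exact binomial test). Chromosome IV held 100 (15.1% against 16.4%, exact binomial test, adjusted p = 0.373). By class, the X held 32.2% of the 180 peaks at small RNA genes, 14.6% of the 308 other promoter peaks and 26.9% of the 175 peaks at neither. Of the 612 tRNA genes, 45.1% are on the X. The third of each autosome around its centre held, over the 5 autosomes, 192 of 513 autosomal peaks (37.4% against 33.3%, permutation p = 0.192, two-sided), which did not pass the threshold; among the 331 strongest nuclear peaks the share was 42.5% (permutation p = 0.0070) and in the list of replicate 2 alone it was 42.1% (permutation p = 0.0164).

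Summits were richer in G and C than the sequence beside them. The GC content was 48.8% ± 7.84 (SD over 663 peaks) in the summit windows and 37.3% ± 9.59 in the windows 200 bp away, and was higher at the summit in 542 peaks (exact sign test, p = 5.32e-69). Of the 2080 words of 6 bases, 322 were more frequent at summits and 247 less frequent at the adjusted threshold. Of these, 241 of the 322 hold 4 or more G or C, and 233 of the 247 hold 4 or more A or T. The tests of words and motifs were not adjusted for GC content. CGCGCA was present at 94 summits and in 10 flanks, GCGCAC at 95 and in 14, and CGAACC at 72 and in 9, whereas TTAAAA was present at 51 summits and in 168 flanks. Among the known motifs, the B box of RNA polymerase III promoters was present at 61 summits and in 3 flanks (exact sign test, adjusted over the list alone, p = 3.07e-15), or at 9.20% of summits, against 5.28% in the list of replicate 2 alone. Without the peaks at small RNA genes, its share fell to 0.621% of summits and missed the threshold. The GAGA motif was present at 147 summits and in 62 flanks (exact sign test, adjusted p = 3.19e-10) and the SP1 motif GGGCGG at 64 and in 16 (adjusted p = 5.66e-07). The E2F core was present at 48 and in 15, and TGTCTC at 76 and in 33; TGTCTC missed the threshold among the 331 strongest peaks (exact sign test, adjusted p = 0.166). The GATA word TGATAA was present at 16 and in 45 (exact sign test, adjusted p = 0.0011) but missed the threshold in windows of 25 bp each side (adjusted p = 0.0727), and the T block was less frequent too, at 172 and in 259. The homeodomain word TAATTA (12 and 31) and the caudal word TTTATG (30 and 57) were also lower (adjusted p = 0.0145 for each, exact sign test), but TAATTA missed the threshold in the list of either replicate alone (adjusted p = 0.141 for replicate 1 and 0.334 for replicate 2, exact sign test). TTTATG missed it in the list of replicate 1 alone (adjusted p = 0.190, exact sign test), and both words missed it among the 331 strongest peaks, in windows of 25 bp each side and without the peaks at small RNA genes.

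The tagged gene itself held no promoter peak. K09A11.1 (WBGene00010704) lies on chromosome X 13262495 to 13264589 on the plus strand, and 1 thresholded peak lay within 20 kb of it, in the promoter of hpl-1, a heterochromatin protein 1 gene named after its value was seen, with a signal of 32.4. As many or more peaks lay within 20 kb of 24.2% of all protein-coding genes. The highest candidate region within 20 kb was not the same site in every list. In the replicate 2 list and the pooled list it was at the hpl-1 peak, with summits at 13245354 and 13245357, and ranked 383 and 623. In the replicate 1 list it was another site, with its summit at 13258679 and a signal of 15.4, and ranked 1332.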

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

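All tests of explanations below were chosen after the results were seen, except the comparison of tRNA and snoRNA genes with and without identical copies, whose bounds were set before that value was known. The design has a single group, so no biological explanation was tested for any of these patterns.

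Peaks on the mitochondrial genome stand out because 26 of the 689 peaks lie there, outside the main location and gene comparisons, and no control library was analysed here to set them against. They include the 10 strongest peaks, with signals up to 452, and the pooled list's regions cover 52.03% of the 13794 bp of that genome. More mitochondrial DNA in the tagged samples than in the control remains open. The coverage lay between bounds chosen after it was known, 75% or more for such an excess and 25% or less against it. All 26 mitochondrial entries of the pooled list (100%), some of which share 1 interval, were past the threshold, against 2.21% of its nuclear entries. This follows from their high signal and does not separate the explanations. Enrichment at fixed positions was seen: 65.4% of the mitochondrial summits of replicate 1 lay within 100 bp of one of replicate 2, against a mean of 39.3% over all circular shifts (permutation p = 0.0050, one-sided). Uneven mapping of reads would give fixed positions as well, so neither explanation is excluded.

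Peaks at tRNA and snoRNA genes may in part come from reads shared between identical gene copies. Of the tRNA and snoRNA genes without an identical copy 12.7% carried a peak, against 24.7% of those with one (Fisher's exact test, p = 1.87e-06), and among tRNA genes alone the shares were 11.9% and 24.7% (p = 0.000774). Shared reads do not account for the snoRNA genes, none of which has an identical copy and 13.0% of which carried a peak; 43 of the 44 peaks at these remain once every peak with a repeated 32-base word in its summit window is left out. Of the 123 tRNA peaks 20 remain then, against 1.36 after shifting (permutation test, adjusted p = 0.00035). A less strict filter left out only peaks whose summit window consists largely of repeated words. With it, 72 of the 123 remain, against 1.66 after shifting (permutation test, adjusted p = 0.00035). The number of tRNA peaks open to shared reads therefore depends on the filter. Shared reads stay open for the tRNA peaks with any repeated word. Recovery of open or highly transcribed chromatin whatever the tag remains open: muscle genes carried promoter peaks at 3.13%, with an interval from 0.381% to 10.8% that holds the 2.49% of other genes. This interval is too wide to decide. Of the 33 gene lists, 7 lay above other genes, among them ribosomal proteins at 29.6% and chaperones at 21.3%. Such recovery could give these shares too. Transcript levels were not analysed, so the gene lists do not separate it from binding by the tagged protein. A precipitation from untagged animals, not analysed here, would bear on such recovery.

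The share of peaks on the X is not accounted for by peaks at small RNA genes alone, since without them the X share was still above its share of coding genes (19.05% against 13.7%, exact binomial p = 0.0011). Whether small RNA genes together with the length of the X explain it is left open by the remaining peaks as a whole: their X share was not distinguishable from the share of chromosome length (19.05%, interval 15.6 to 22.8, against 17.7%, exact binomial p = 0.438), but the interval also holds the 22.6% of all nuclear peaks. The 175 peaks at neither a promoter nor a small RNA gene lay on the X more often than the X share of such sequence. Of these peaks, 26.9% are on the X (interval 20.4 to 34.1). The X holds 18.7% of the sequence outside promoters and small RNA genes (exact binomial p = 0.0084). This sequence includes exons, which held 2.86% of these peaks, and the X share of it without exons was not computed. The explanation is therefore not settled for these peaks either. The other 308 peaks, at promoters, had 14.6% on the X (interval 10.9 to 19.1). This was not distinguishable from the 13.7% of coding genes (exact binomial p = 0.619). The excess over coding genes that remained therefore lay in the peaks at neither. Extra copies of the tagged region in the transgene are argued against only as the source of most of the excess of 59.3 X peaks. Of this excess, 3.37% lay within 50 kb of K09A11.1. A window of this size could hardly hold much of the excess, so a local effect of the copies is not addressed. The window held 2 peaks, and 15.4% of genes had as many or more.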

How the results depend on the processing

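The alternatives without peaks at small RNA genes, without peaks in repeated sequence or with any repeated word, and with the mitochondrial peaks were chosen after seeing the data. The promoter share, the divergent promoter share and the overlap of the replicate lists kept their direction and stayed past the threshold in every alternative run. So did the X share, except without peaks at small RNA genes and against chromosome length together, at 19.05% against 17.7% (exact binomial, adjusted p = 0.438), where removing 180 peaks, 32.2% of them on the X, and raising the expectation ended the call. The promoter share ranged from 51.3% to 57.2% over the replicate lists alone, the divergent share from 31.8% to 35.4% and the X share from 20.8% to 23.7%. Noncoding classes past the threshold numbered 5 in each alternative, and the ce10 list held 705 peaks. The share around the centres of autosomes passed the threshold at 42.5% among the 331 strongest nuclear peaks and ranged from 37.1% (replicate 1, permutation p = 0.122) to 42.1% (replicate 2, permutation p = 0.0164, past the threshold) over the replicate lists; against coding genes, 38.1% of which lie there, the 37.4% was below expectation (exact binomial p = 0.785). Gene lists past the threshold fell from 9 to 3 among the 331 strongest, and numbered 8 and 10 in the replicate lists, sharing 7 and 8 with the full set. Proteasome genes fell to 0% with isolated promoters as background, where 6 of the 33 members were left and 1.24% of other genes had a peak (Fisher's exact test, adjusted p = 1), too few for a peak to be expected. Words past the threshold numbered 569, against 280 among the 331 strongest, 320 in windows of 25 bp each side and 367 without peaks at small RNA genes, and 504 to 512 in the replicate lists. The strength trend, not past the threshold, was -0.036 among the 331 strongest and 0.047 to 0.066 in the replicate lists. At least as many peaks lay within 50 kb as at K09A11.1 for 15.4% of genes. Of 174 alternatives for named lists, classes and motifs, 146 kept direction and side of the threshold, 27 lost significance and 1, that of the proteasome genes, reversed. A stricter IDR was not run, because the list used here has no IDR score column. No paired analysis was possible because there is 1 group. Without counts, depth sets no stated limit on any value.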

Other observations

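The 175 nuclear peaks at neither a promoter nor a small RNA gene held GAGAGA at their summits in 55 cases against 16 flanks (exact sign test, adjusted p = 8.39e-05) and AGACGC in 28 against 5 (adjusted p = 0.0088), and both words were also more frequent at the summits of the 308 promoter peaks (GAGAGA 69 against 28, adjusted p = 9.48e-05; AGACGC 37 against 8, adjusted p = 0.000133). Among the leading words at promoter peaks, GCGCAC (71 against 7) and CTTGCA (58 against 4) were at 9 against 3 and 6 against 2 of the peaks at neither, and missed the threshold there. Differences between the classes were not tested. Introns held 73 of these 175 peaks, and the GC content was 46.3% ± 8.54 (SD over peaks) at the summits and 39.6% ± 9.45 beside them. In 18.3% of them at least 50% of the 32-base words of the summit window recurred elsewhere in the genome, compared with 1.95% of promoter peaks and 28.9% of peaks at small RNA genes.

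Peaks at small RNA genes had a median signal of 54.6, against 42.3 at other promoters and 43.4 at neither, a difference that was not tested. They made up 43.6% of the fifth of highest signal and 15.9% of the fifth of lowest signal. Peaks were found at tRNA genes of many products, from 9 of 27 tRNA-Asp genes to 1 of 12 tRNA-Trp genes, and no product differed from the others past the threshold (Fisher's exact test, lowest adjusted p = 0.940). The single tRNA-Trp gene with a peak was sup-5, named after its value was seen, with a signal of 94.97. At the sup-5 peak, 74.3% of the 32-base words of the summit window recurred elsewhere in the genome. Reads there may therefore not be placed uniquely. No snoRNA gene with a peak was on the X, which holds 33 of the 346 snoRNA genes.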
